A study of Oreochromis niloticus with 8 samples.

How the data were processed

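Midbrain polyadenylated RNA of Nile tilapia (Oreochromis niloticus) was measured by RNA sequencing in 8 libraries, 4 from fish kept at normothermy (control) and 4 from cold-exposed fish (cold). Groups and replicate numbers were taken from the sample labels. Per the labels' protocols, RNA was extracted with TRIzol, messenger RNA was captured with poly(dT) beads and libraries were made with an Illumina TruSeq RNA kit. HISAT2 is named in the submitters' processing notes. The program that counted reads, the genome build, the annotation, the software versions and the handling of strand and multiply mapped reads are not given in the sources used here. The temperature, the length of the exposure and the time of day at collection are not given there either.

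The authors deposited 1 list of TPM values (transcript abundances scaled by gene length and by library total) per library, each with 29533 genes and no header. The unit was read from the values: every deposited TPM list summed to 1000000, and low values were not multiples of a common step. TPM keeps no absolute depth. The ratios between libraries of the low values of the same genes gave approximate depths of 0.859 (control 2) to 1.04 (control 4) times that of control 1, and between 17842 and 18506 genes reached 1 TPM in each library. Genes listed by an identifier starting with LOC numbered 19370, of which 19368 were found in the reference gene table of assembly O_niloticus_UMD_NMBU and 6153 received a symbol there. That table was used for names and gene spans only, and no coordinates are printed because the build behind the files is not named. Reads from near-identical gene copies (a and b copies, numbered copies) or from overlapping genes could have been divided or shared in the counting, so values of single copies are uncertain.

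The test planned before the data were examined was a count test, with limma on log2 values as the fallback for normalized values. Because the values were TPM, the fallback was used. limma 3.58.1 in R 4.3.3 was fitted to log2(TPM + 1) with the trend option and robust set off, cold against control, without covariates, over all 8 libraries. Genes with a mean of at least 1 TPM in either group were tested (18863 genes, 14140 of them with a symbol). Tests were two-sided, p was adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. All log2 changes are cold minus control on the log2(TPM + 1) scale, which understates changes of low genes. Errors of means are SD and errors of log2 changes are standard errors (SE), with 4 libraries per group.

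Before the data were examined, 45 gene lists (pathways, and markers of brain regions and of other cell types) were fixed. Symbols were matched with the copy suffixes of fish genes and the synonyms of the reference table. Genes without a symbol joined a list only through such a synonym. The plan to let them join through their product descriptions was not followed. The suffix rule took in 10 genes that differ from the gene meant, among them the GTPase genes rhoaa, rhoab and rhob in the photoreceptor list. The lists were kept as fixed, and an alternative left these genes out. Lists were tested with limma's camera with a preset correlation of 0.01, and again with a correlation estimated for each list. They were also tested with fry, which asks whether a list's members move on balance in 1 direction without comparing them with other genes. Members called by the gene test were counted, with p adjusted over all genes tested and adjusted over the list alone.

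Genes named in the text followed a rule written before the data were examined. It took the 8 largest rises and 8 largest falls among called genes with a symbol, a mean of at least 2 TPM in a group and no overlap between groups. It also took up to 4 called members of lowest p in each list, all tested members of the oxytocin and vasotocin list, and the 2 most highly expressed members of each marker list. Some genes that this rule takes in are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

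The gene test was tested on simulated data for this comparison, with the means and spread of the 18863 genes and 200 changed genes. limma recovered 13.4% of genes changed 1.5-fold, 62.7% of those changed 2-fold and 90.9% of those changed 4-fold, and 5.13% of its calls were false. The unchanged genes, rescaled to a fixed total, had a median log2 change of -0.0993. These rates belong to 200 changed genes, with genes varying independently of each other. In the real data limma called 6914 genes, so the rates may differ there. The list test was tested on other simulated values, again with independent genes, where an added list of 40 genes was raised 1.3-fold. That list passed camera with the preset correlation as higher (adjusted p = 2.69e-59), and 0 other lists were called. The labels give both groups the replicate numbers 1 to 4. Whether these numbers pair the libraries was checked from the correlations of same-numbered libraries, and no pairing was found. Alternatives covered the scaling of the values, the filter, the pseudocount, library weights, the replicate number as a block, thresholds, the set test, and each library left out in turn. Count-based alternatives planned for read counts were not run, since they need counts. Comparisons of oxt and avp values between groups used exact permutation tests over all 70 assignments of the 8 libraries, two-sided.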

Results

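The midbrain transcriptome of Nile tilapia, a warm-water cichlid, was measured in 4 control libraries from fish kept at normothermy and 4 cold libraries from cold-exposed fish. The series title names oxytocin signalling in the homeostatic response to cold as its subject, so the comparison of cold with control answers which midbrain transcripts differed after cold exposure, the oxytocin system among them. The labels do not say whether each library came from a single fish, so p-values measure the spread between these 8 libraries. Each library's TPM values sum to a fixed total and absolute depth is unknown. Libraries of the same group correlated more closely (r of log2 values from 0.968 to 0.982) than libraries of different groups (0.943 to 0.963), and no library duplicated another. The first principal component held 43.4% of the variance and separated the groups. The second held 16.9%, and on it control 4 (-31.3) and cold 2 (-33.3), one from each group, stood apart from the other 6 libraries.

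Cold exposure was accompanied by large changes in clock-related and stress-related transcripts. Among genes with a symbol, the circadian repressor gene nr1d1 rose most, from 3.77 ± 1.099 to 73.1 ± 6.29 TPM (SD, n = 4 per group), a log2 change of 3.98 ± 0.15 (SE). Next came hamp, the gene of the iron hormone hepcidin (3.30 ± 3.32 to 49.6 ± 20.9 TPM), and ciarta, a gene of another circadian repressor (17.4 ± 3.32 to 231 ± 12.4 TPM). The largest falls among genes with a symbol were those of p2ry12, a microglial purinergic receptor gene (25.2 ± 4.67 to 2.25 ± 0.589 TPM, log2 change -3.01 ± 0.17), and chrnb1l, named after an acetylcholine receptor subunit (8.53 ± 4.25 to 1.32 ± 2.51 TPM). The gene safb2, which encodes a nuclear RNA-binding protein, fell from 439 ± 22.5 to 89.99 ± 9.51 TPM.

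Also among genes with a symbol, the other largest rises were those of sertad1 (9.12 to 79.5 TPM), mafk (1.46 to 16.1 TPM), espnlb (1.26 to 14.0 TPM), rnf227 (38.5 to 236 TPM) and dbpb, a gene of a clock-controlled transcription factor (53.5 to 328 TPM). The other largest falls were those of the monocarboxylate transporter gene slc16a1a (8.54 to 0.804 TPM), fhl5 (5.79 to 0.462 TPM), lgals3bp.3 (15.7 to 2.77 TPM), ppp1r10, a gene of a nuclear regulator of protein phosphatase 1 (35.6 to 8.17 TPM), and the hypothalamic transcription factor gene nkx2.4a (25.7 to 5.97 TPM). limma's adjusted p lay between 3.83e-07 for ciarta, dbpb and ppp1r10 and 0.01002 for chrnb1l, whose level in cold 3 (5.08 TPM) was far from the other cold libraries (0.0593 to 0.0634 TPM). Among genes without a symbol, LOC100709437 (2.95 to 237 TPM) and LOC100707699 (7.47 to 430.3 TPM) rose most, and LOC100695906 (89.3 to 9.86 TPM) and LOC100695806 (21.5 to 2.39 TPM) fell most.

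In all, limma called 6914 of 18863 genes (36.7%), 2455 higher and 4459 lower in cold, and 64.5% of the called genes were lower. Counts of called list members given below are to be read beside these shares of all genes. With values rescaled by the median of ratios, 3407 were higher and 3295 lower (49.2% lower), and 5750 genes kept their call and direction. The excess of falls over rises therefore depends on the scaling. At least 2-fold differences on the log2(TPM + 1) scale were held by 267 called genes that rose and 346 that fell. Group values did not overlap for 6958 genes (36.9%, against 2.86% by chance). The median log2 change of all tested genes was -0.09.

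**Figure D1:**
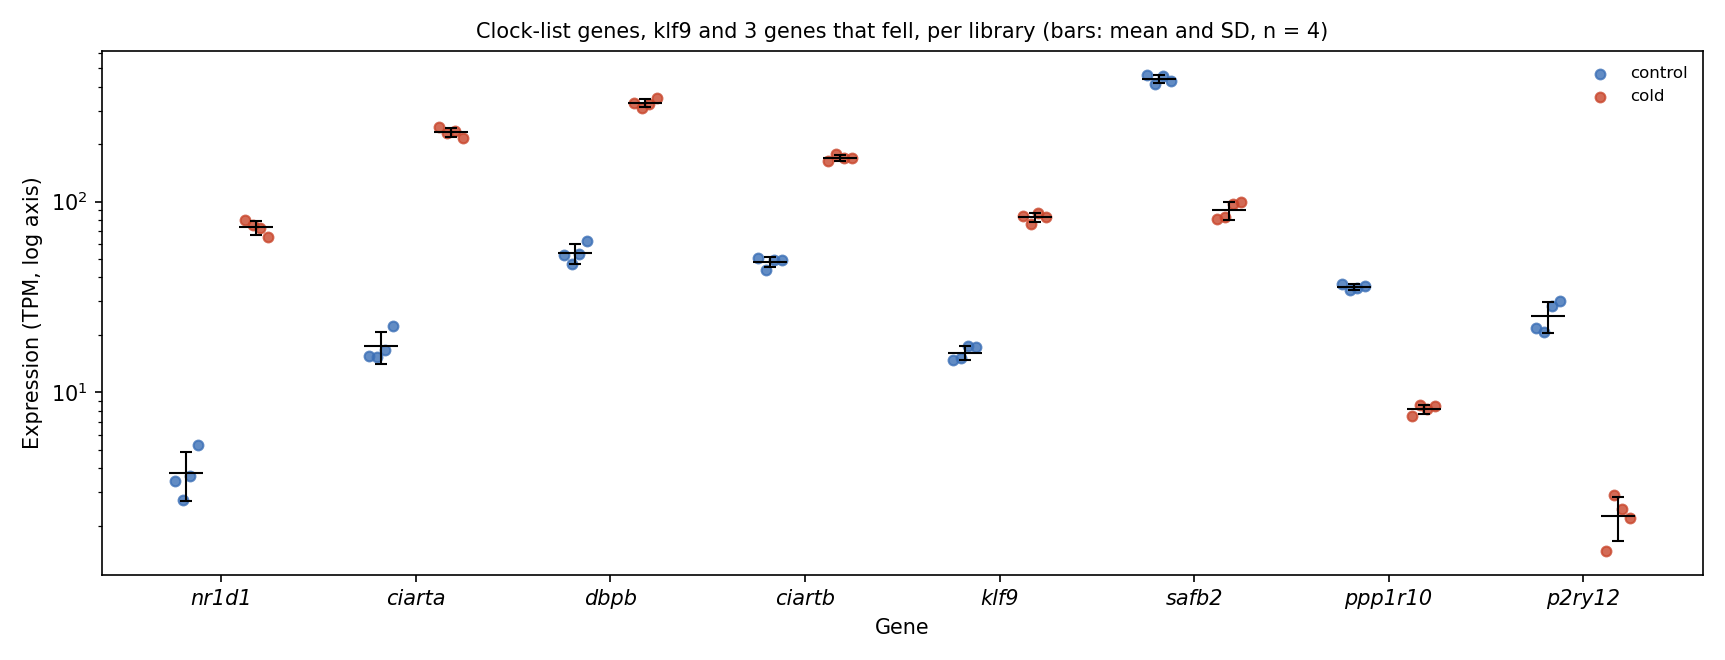
Expression (TPM, log axis) of 8 genes in the 4 control libraries (blue points) and 4 cold libraries (red points), with black bars for the mean and SD. In nr1d1, ciarta, dbpb, ciartb and klf9 all cold points lie above all control points, and in safb2, ppp1r10 and p2ry12 all lie below.

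The receptor genes avpr1a and oxtr fell, and no difference was detected in the peptide genes oxt and avp. Of 7 tested members of the oxytocin and vasotocin list, 1 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.944). The vasotocin receptor gene avpr1a fell from 2.63 ± 0.337 to 1.249 ± 0.317 TPM (log2 change -0.70 ± 0.14, limma adjusted p = 0.00550), and the oxytocin receptor gene oxtr fell from 4.93 ± 0.621 to 3.29 ± 0.660 TPM (-0.47 ± 0.14, limma adjusted p = 0.0242). The gene lnpep, which encodes the aminopeptidase known as oxytocinase, rose from 26.1 ± 1.39 to 34.7 ± 2.24 TPM (0.40 ± 0.07, limma adjusted p = 0.00192). Levels of avpr2aa were 2.65 ± 0.333 and 1.90 ± 0.725 TPM and those of avpr2b.1 were 1.39 ± 0.406 and 0.930 ± 0.280 TPM in control and cold, with limma adjusted p of 0.155 and 0.210. The call of oxtr was lost when control 2, control 4, cold 2 or cold 4 was left out (limma adjusted p = 0.0650, 0.0607, 0.0556 and 0.0582), and when control 4 and cold 2 were left out together (log2 change -0.36, adjusted p = 0.113), while avpr2aa (log2 change -0.51) passed without cold 4 (0.0349).

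The oxytocin gene oxt (named for isotocin in fish) measured 767 ± 556 TPM in control and 1729 ± 1966 TPM in cold, and the vasotocin gene avp measured 875 ± 683 and 896 ± 406 TPM. Neither difference passed (log2 change 0.84 ± 0.82 and 0.38 ± 0.61, limma adjusted p = 0.455 and 0.667; exact permutation p = 0.400 and 0.571). Within groups oxt ranged 5.07-fold in control and 12.01-fold in cold, and the highest value, 4607 TPM, came from cold 2. Without cold 2 the log2 change of oxt was 0.14, and without control 1 that of avp was -0.07. The ratio of oxt to avp was 7.25 in cold 2 and between 0.641 and 1.24 in the other 7 libraries, and its difference between groups gave an exact permutation p of 0.943. The share of called genes in oxytocin receptor signalling was near the 36.7% of all tested genes. Among 96 tested genes of this list, 9 rose and 27 fell, with the same counts adjusted over the list alone. Those of lowest p were the inhibitory G protein gene gnai1 (78.6 to 44.7 TPM), the adenylate cyclase gene adcy7 (27.4 to 19.3 TPM), the kinase gene camk1a (44.7 to 31.6 TPM) and the cell cycle inhibitor gene cdkn1a, which rose (4.30 to 11.9 TPM). As a set this list did not pass limma's camera (adjusted p = 0.274), though fry, which compares it with no other genes, called it lower (adjusted p = 0.00645). After median-of-ratios scaling 11 rose and 19 fell.

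**Figure D2:**
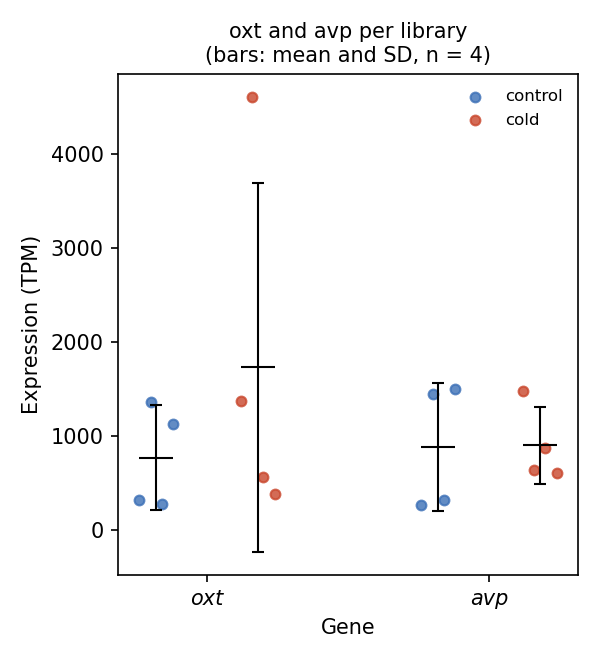
Expression (TPM, linear axis) of oxt and avp in the 4 control (blue) and 4 cold (red) libraries, with black bars for the mean and SD. The value of oxt in cold 2, 4607 TPM, lies far above the other 7, and the groups overlap for both genes.

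Clock genes and genes induced by cell activity or glucocorticoids held more rises than falls. As lists they passed camera with the preset correlation but not with an estimated one. Of 37 tested clock genes, 21 rose and 3 fell, with the same counts adjusted over the list alone. The lowest p of the list belonged to ciarta, dbpb and ciartb (48.3 ± 3.04 to 169.7 ± 6.21 TPM, limma adjusted p = 3.83e-07), followed by nr1d1 (limma adjusted p = 1.06e-06). Named after their values were seen, tef (101 to 455 TPM), bhlhe40 (59.9 to 322 TPM) and per2 (9.599 to 15.5 TPM) rose, and the falls were those of per3 (132 to 82.4 TPM), rorc (5.53 to 1.40 TPM) and csnk1db. The core activator arntl measured 15.3 ± 2.30 TPM in control and 18.0 ± 0.863 TPM in cold (limma adjusted p = 0.112). The clock list passed limma's camera (adjusted p = 2.15e-09), though not with an estimated correlation (adjusted p = 0.0661).

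Of 43 immediate-early genes, which respond within minutes to cell activity, 27 rose and 3 fell (31 and 3 adjusted over the list alone). Examples are the transcription factor gene klf6a (32.9 to 64.7 TPM), the matrix protein gene cyr61 (11.99 to 42.8 TPM), the kinase gene pim1 (39.3 to 68.5 TPM) and socs3, a brake on cytokine signalling (29.2 ± 3.17 to 89.1 ± 16.6 TPM). Fos and Egr genes, chosen after their values were seen, included egr1 (69.8 to 133 TPM) and fosab (15.9 to 42.0 TPM), both of which rose. The falls were those of nr4a2, ier5l and klf4. Of 32 glucocorticoid-response genes, 15 rose and 2 fell (17 and 2 adjusted over the list alone), led by klf9 (16.1 ± 1.42 to 82.5 ± 4.61 TPM), the phosphatase gene dusp1 (14.0 to 49.4 TPM), fkbp5, which encodes a chaperone of the glucocorticoid receptor (245 to 543 TPM), and cebpb (23.1 to 45.9 TPM). The falls were the glutamine synthetase copies glula and glulb. By limma's camera the adjusted p was 1.10e-10 for immediate-early genes and 3.16e-06 for glucocorticoid-response genes. Neither list passed with an estimated correlation (adjusted p = 0.300 for both).

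Some genes of growth arrest and apoptosis, such as ccng2, and of the cell cycle, such as chaf1a and pcna, rose. In the p53, apoptosis and growth arrest list, 20 of 38 members rose and 1, rps27l, fell (22 and 1 adjusted over the list alone). They included ccng2 (8.73 to 21.2 TPM), tp53inp1 (15.3 to 27.3 TPM), gadd45b (48.3 to 104 TPM) and the caspase gene casp3a (22.7 to 42.3 TPM). In the cell cycle list, 16 of 55 members rose and 5 fell, with the same counts adjusted over the list alone. The rises of lowest p were those of the chromatin assembly gene chaf1a (7.22 ± 0.119 to 20.04 ± 1.496 TPM), e2f1 (1.51 to 4.87 TPM), gins1 (13.04 to 25.9 TPM) and pcna (31.6 to 62.1 TPM), which act in DNA synthesis and in repair. The falls were those of the neural stem cell gene sox2, rrm2b, hells, cdk4 and rfc2. The suffix rule took in rrm2b for rrm2, a different gene, and without it the list still passed limma's camera (adjusted p = 0.00124). The adjusted p of limma's camera was 3.73e-07 and 0.00196, and 0.169 and 0.387 with an estimated correlation.

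Genes for making ribosomes, for protein breakdown and for autophagy also held more rises than falls. In ribosome biogenesis 17 of 66 rose and 7 fell, with the same counts adjusted over the list alone, among them rcl1 (37.3 to 87.6 TPM), the nucleolin gene ncl (218 to 319 TPM), nop56 (60.2 to 94.9 TPM) and imp4 (12.7 to 24.5 TPM). In the proteasome list 8 of 44 rose and 3 fell (8 and 2 adjusted over the list alone; 18 and 1 after median-of-ratios scaling). The subunit genes psmd6 (124 to 167 TPM), psmd13 (135 to 165 TPM) and psmb1 (125 to 149 TPM) rose, and nfe2l1, a transcriptional activator of proteasome genes, fell (53.3 to 33.7 TPM). In autophagy 15 of 46 rose and 8 fell (16 and 10 adjusted over the list alone; 20 and 3 after median-of-ratios scaling), with the receptor genes optn (17.0 to 33.0 TPM) and sqstm1 (79.9 to 123 TPM), atg9b (16.1 to 26.0 TPM) and ulk2 (31.9 to 42.8 TPM) among the rises. limma's camera gave an adjusted p of 0.00196 for ribosome biogenesis, 0.00196 for the proteasome and 0.0271 for autophagy, against adjusted p of 0.169, 0.404 and 0.846 with an estimated correlation. None of the 80 cytosolic ribosomal protein genes was called by limma, or when adjusted over the list alone. That list nevertheless passed camera as a set (adjusted p = 0.00698, mean log2 change 0.04; adjusted p = 0.862 with an estimated correlation, 0.433 by fry). It did not pass without control 2 (0.0570) or cold 2 (0.178), and 8 of its members rose after median-of-ratios scaling, while 1 member was called without control 1.

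Cold-inducible genes, heat shock genes and splicing genes moved in both directions. The gene cirbp, which encodes the cold-inducible RNA-binding protein, rose from 2479 ± 192 to 5079 ± 416 TPM (log2 change 1.03 ± 0.08, limma adjusted p = 4.64e-05). The RNA helicase gene ddx3x (134 to 276 TPM) and the chromatin protein gene hmgb1a (531 to 1001 TPM) also rose, and the kinase gene clk4a fell (488 to 208 TPM). These belong to a list of 19 cold-inducible RNA-binding and chromatin genes, of which 3 rose and 6 fell (4 and 6 adjusted over the list alone). Of 41 heat shock genes 8 rose and 18 fell, with the same counts adjusted over the list alone. The falls included the Hsp40 gene dnajb1a (11.6 ± 0.107 to 2.86 ± 0.406 TPM), the Hsp90 gene hsp90aa1.2 (464 to 265 TPM) and the collagen chaperone gene serpinh1 (25.9 to 6.31 TPM), and the rises included LOC100700083, which has the synonym Hsp70 in the reference (12.6 to 31.3 TPM).

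In the endoplasmic reticulum stress list 12 of 44 rose and 12 fell (14 and 12 adjusted over the list alone), with rises of trib3 (1.98 to 7.47 TPM) and edem1 (7.64 to 14.4 TPM) and falls of the sensor gene atf6 (24.2 to 14.0 TPM) and sdf2l1 (44.1 to 30.5 TPM). Of 75 splicing genes 19 rose and 26 fell (23 and 29 adjusted over the list alone). The splicing regulator genes srsf1a (109.7 to 53.5 TPM), srsf2a (156 to 72.4 TPM) and luc7l3 (160.3 to 87.5 TPM) and the kinase gene prpf4b (36.6 to 20.5 TPM) fell, whereas cdc5l and the spliceosome gene snrpg, chosen after their values were seen, rose (39.8 to 59.8 and 147 to 193 TPM). The suffix rule took in prpf4b for prpf4, a different gene. After median-of-ratios scaling the splicing counts turned to 27 rises and 21 falls and the endoplasmic reticulum counts to 18 and 6, and the heat shock counts became 11 and 13. limma's camera called none of these lists (adjusted p = 0.681 for cold-inducible, 0.398 for heat shock, 0.201 for endoplasmic reticulum and 0.990 for splicing genes). By fry the heat shock (adjusted p = 0.00188) and splicing genes (0.0458) were lower, and the other lists did not pass (0.360 for cold-inducible and 0.237 for endoplasmic reticulum genes).

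Genes of sterol synthesis fell more often than they rose. In the cholesterol list 5 of 27 rose and 12 fell (5 and 14 adjusted over the list alone). The gene sqle of squalene epoxidase fell from 8.31 ± 2.13 to 1.58 ± 0.248 TPM (log2 change -1.83 ± 0.17), and nsdhl (5.002 to 1.37 TPM) and cyp51 (22.4 to 8.77 TPM), chosen after their values were seen, fell too. Rises were those of idi1 (31.8 to 54.1 TPM), acat2 (58.0 to 99.99 TPM), insig1, a brake on sterol synthesis (20.8 to 45.3 TPM), insig2 and ldlrb. In fatty acid synthesis 6 of 30 rose and 6 fell, with the same counts adjusted over the list alone (7 and 5 after median-of-ratios scaling). The desaturase gene scd rose (126 to 189 TPM), while the elongation genes hacd3 (49.9 to 26.9 TPM), hsd17b12b (90.6 to 67.4 TPM) and elovl6 (135 to 110.2 TPM) fell. In phospholipid remodelling 7 of 35 rose and 6 fell (7 and 7 adjusted over the list alone; 10 and 3 after median-of-ratios scaling), with rises of chka (109 to 166 TPM), ptdss2 (22.9 to 39.0 TPM), lpin1 (10.6 to 17.2 TPM) and pnpla6 (45.8 to 55.5 TPM). limma's camera called none of these lists (adjusted p = 0.434, 0.511 and 0.274).

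Some energy metabolism genes, such as sdhb and pfkfb3, changed. In oxidative phosphorylation 1 of 77, cox4i2 (186 to 223 TPM), rose and 6 fell (0 and 2 adjusted over the list alone), among them sdhb (135 to 105 TPM) and ndufs1 (48.6 to 36.5 TPM), but after median-of-ratios scaling 11 rose and 2 fell. The 7 calls became 4 without control 1, control 2, cold 2, cold 3 or cold 4. In glycolysis 2 of 33 rose, pfkfb3 (11.9 to 28.1 TPM) and pfkfb4b (102 to 143 TPM), and 5 fell, among them slc16a1a and the phosphofructokinase gene pfkpa (249 to 207 TPM). These counts were 2 and 3 adjusted over the list alone, and 4 and 3 after median-of-ratios scaling. In fatty acid oxidation 4 of 34 rose and 7 fell (3 and 6 adjusted over the list alone; 8 and 5 after that scaling), with falls of hsd17b4 (31.2 to 23.9 TPM), decr1 (35.3 to 25.2 TPM) and cpt2 (10.4 to 7.54 TPM), and 7 calls were left without cold 1. In the hypoxia list 4 of 30 rose and 6 fell (6 and 6 adjusted over the list alone; 8 and 2 after that scaling), with falls of hif1a (85.5 to 66.5 TPM) and p4ha2 (7.22 to 3.83 TPM). In the thyroid and uncoupling list 2 of 18 rose and 4 fell, with the same counts adjusted over the list alone (3 and 2 after that scaling). The rises were klf9 and slc25a14 (21.1 to 29.1 TPM), and the falls were atp2a2a (78.0 to 64.0 TPM), dio2, thrap3a and slc25a5 (limma adjusted p = 0.0518 after that scaling, 0.0728 without control 4 and cold 2). None of these lists passed limma's camera (adjusted p = 0.399, 0.483, 0.944, 0.434 and 0.661).

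GABA receptor genes such as gabrb2 fell, as did some genes of other neuronal receptors and channels, such as htr1a and hcn2. Of 36 tested GABA and glycine genes 19 fell and 1, glra4a, rose (22 and 2 adjusted over the list alone). The GABA receptor subunit gene gabrb2 fell from 382 ± 18.5 to 256 ± 16.9 TPM (log2 change -0.58 ± 0.06), gabrb2b from 40.7 to 26.0 TPM and the GABA transporter gene slc6a13 from 26.3 to 17.2 TPM. This list passed limma's camera (adjusted p = 0.00198; adjusted p = 0.422 with an estimated correlation), and after median-of-ratios scaling 11 members fell and 1 rose. Without control 1 or control 2, 13 GABA and glycine genes were called in all. Of 60 voltage-gated channel and sodium pump genes 20 fell and 1, kcna1a, rose, with the same counts adjusted over the list alone (11 and 2 after median-of-ratios scaling; 12 called in all without control 1), including hcn2 (6.63 to 3.80 TPM), slc12a5a (176 to 127 TPM), kcna3a (3.69 to 1.48 TPM) and kcnh5 (10.9 to 6.89 TPM). Of 60 monoamine and acetylcholine genes 16 fell and none rose (13 and 0 adjusted over the list alone; 11 and 1 after median-of-ratios scaling), led by the serotonin receptor genes htr5a (7.33 to 2.74 TPM), htr1a (9.15 to 3.81 TPM) and htr1b (15.9 to 10.5 TPM) and the adrenergic receptor gene adra2b (30.2 to 20.2 TPM). Of 25 genes of thermosensitive channels 10 fell, among them ano1b (7.81 to 2.79 TPM), kcnk2a (8.45 to 2.70 TPM) and kcnk2 (14.6 to 10.3 TPM), and 2 rose, trpc1 (49.2 to 60.2 TPM) and trpc6a, with the same counts adjusted over the list alone. The call of trpc1 was lost without control 4 and cold 2 together (log2 change 0.23, limma adjusted p = 0.0518). Of 47 glutamate genes 7 fell and 2, shank2 (36.2 to 44.0 TPM) and grik4, rose, with the same counts adjusted over the list alone. Falls included grik3 (28.9 to 16.9 TPM) and grm2b (129 to 85.8 TPM), and 4 rose and 4 fell after median-of-ratios scaling, while 15 were called in all without cold 2. These 4 further lists did not pass limma's camera (adjusted p = 0.0695, 0.144, 0.274 and 0.325), though fry called them lower (adjusted p = 0.00645, 0.0251, 0.00724 and 0.0198).

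Transcription factor genes that mark brain regions, such as lhx5 and nr2f2, fell beside these neuronal genes, though most region markers were not called. Of 25 optic tectum and midbrain markers 11 fell and none rose, with the same counts adjusted over the list alone, including the transcription factor genes lhx5 (10.4 to 5.24 TPM), nr4a2 (8.34 to 4.36 TPM), lhx1 (16.3 to 11.2 TPM) and tal2 (8.78 to 4.76 TPM). This list passed limma's camera (adjusted p = 0.0386), though not with an estimated correlation (adjusted p = 0.846) or without control 2 (adjusted p = 0.0841, 7 members called), or with a filter at 5 TPM (adjusted p = 0.0630, 7 members called). Its most highly expressed members, zic1 (304 ± 89.2 and 259 ± 152 TPM) and en1b (27.9 ± 9.37 and 18.5 ± 5.14 TPM in control and cold), were not called. Of 27 telencephalon markers 11 fell and none rose (12 and 0 adjusted over the list alone), with nr2f2 (169.9 to 106 TPM), isl1a (15.01 to 8.06 TPM), prox1 (14.9 to 7.66 TPM) and nr2f1 (94.1 to 65.5 TPM), while zbtb18 measured 149.9 ± 24.8 and 192 ± 50.3 TPM. Of 36 hypothalamic and preoptic markers 12 fell and none rose, with the same counts adjusted over the list alone, including nkx2.4a, six6 (9.23 to 3.36 TPM) and rx3 (2.08 to 0.399 TPM). Of 34 cerebellum markers 7 fell and 1, atoh1 (3.15 to 8.82 TPM), rose (3 and 1 adjusted over the list alone, and after median-of-ratios scaling). Without control 1, control 2 or control 3 the calls became 4, and without cold 1, cold 2 or cold 3 they became 5. The falls included barhl2 (4.36 to 1.67 TPM) and en1a (8.34 to 4.47 TPM), and pvalb7 (808 and 792 TPM) and pcp4 (549 and 545 TPM) were not called. Of 7 hindbrain markers mafb fell (36.0 to 20.2 TPM), also adjusted over the list alone, and mafbb measured 18.7 and 15.2 TPM (limma adjusted p = 0.142; 0.0335 without control 1). Hindbrain calls became 2 without control 1, cold 2 or cold 4, and 3 without control 3. These 4 lists did not pass limma's camera (adjusted p = 0.0901, 0.325, 0.374 and 0.944), but that of the telencephalon passed without control 4 and cold 2 together (0.0103). Of 63 neuropeptide genes 2 rose, sst5 (0.586 to 4.51 TPM) and edn1 (9.46 to 23.7 TPM), and 1 fell, pcsk2 (208 to 182 TPM), against 1 and 0 adjusted over the list alone (camera adjusted p = 0.391). Neuropeptide calls became 5 without cold 1 or cold 2, and 1 without cold 3 or cold 4. The call of edn1 held without control 3 or cold 1 but not without any other library (limma adjusted p from 0.0501 to 0.0984), and that of pcsk2 was lost without control 1 (0.0691), cold 1 (0.0708), cold 3 (0.0622) or cold 4 (0.0614), and after scaling by the median of ratios (log2 change -0.11, adjusted p = 0.218) or the upper quartile (-0.15, 0.0817).

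**Figure D3:**
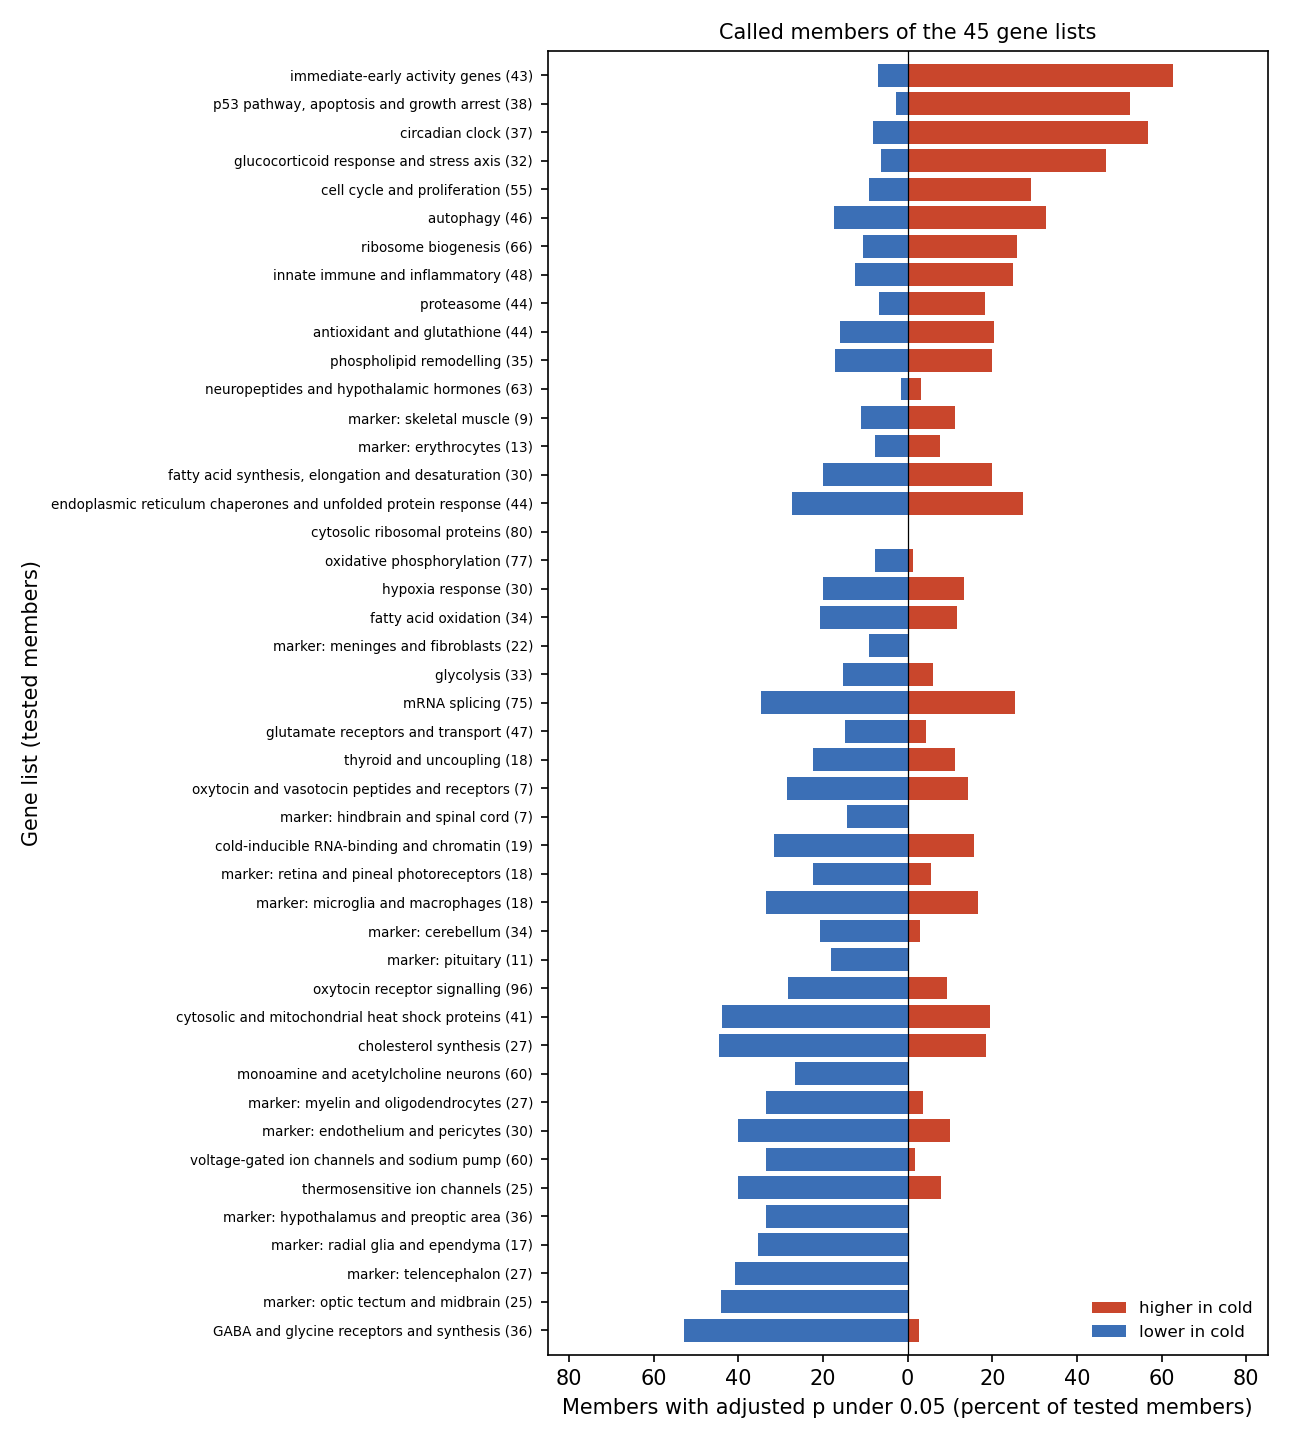
Share of the tested members of each of the 45 gene lists (vertical axis, tested members in parentheses) that limma called higher (red, to the right) or lower (blue, to the left) in cold, as a percent of members. Immediate-early, clock and growth arrest genes reach farthest to the right (27 of 43, 21 of 37 and 20 of 38), and GABA and glycine genes farthest to the left (19 of 36). After median-of-ratios scaling the balance turned to more rises in splicing, oxidative phosphorylation, glycolysis, fatty acid oxidation, hypoxia and thyroid genes, and equal or nearly equal counts became more rises in endoplasmic reticulum, fatty acid synthesis and phospholipid genes.

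Microglial genes and other glial and vascular markers changed in mixed ways. Of 18 microglia and macrophage markers 6 fell and 3 rose, with the same counts adjusted over the list alone. Beside p2ry12 the falls included the myeloid transcription factor genes spi1a (7.67 to 3.24 TPM) and irf8 (12.4 to 6.43 TPM), and the rises were the lysosomal gene hexb (51.8 to 65.4 TPM), aif1l and cd68. The most abundant members, apoeb (1133 ± 230.3 and 1330.1 ± 70.6 TPM) and cd74b (755 ± 223 and 977 ± 155 TPM in control and cold), were not called, but each passed without control 4 (limma adjusted p = 0.00994 and 0.0246). Of 27 oligodendrocyte markers 9 fell and 1, aspa, rose (9 and 2 adjusted over the list alone; 8 and 3 after median-of-ratios scaling). The transcription factor genes olig1 (12.8 to 5.74 TPM), sox10 (22.2 to 12.6 TPM) and olig2 (45.1 to 32.7 TPM) and the precursor receptor gene gpr17 (13.8 to 6.08 TPM) fell, while the myelin genes mbpa (8561 ± 1242 and 8128 ± 1041 TPM) and cd59a (1823 ± 273 and 1888 ± 127 TPM) were not called. Of 17 radial glia markers 6 fell and none rose, with the same counts adjusted over the list alone, among them glula (798 to 405 TPM), sox2 (44.5 to 23.9 TPM), rsph9 (6.94 to 4.00 TPM) and the brain aromatase gene cyp19a1b (433 to 254 TPM). Radial glia calls became 3 with the replicate number as a block, where cyp19a1b lost its call (limma adjusted p = 0.0544). The abundant glial genes s100b (2301 ± 134 and 2202 ± 365 TPM) and fabp7 (1618 ± 111 and 1750.0 ± 346 TPM) were not called. Of 30 endothelial and pericyte markers 12 fell and 3 rose (13 and 3 adjusted over the list alone; 9 and 3 after median-of-ratios scaling). The receptor gene kdr fell (42.8 to 19.8 TPM), and mfsd2a (17.8 to 41.7 TPM), egfl7 (32.5 to 61.5 TPM) and fli1 rose, while cldn5 measured 77.9 ± 16.7 and 59.3 ± 5.82 TPM (limma adjusted p = 0.0795; 0.0130 without control 1). None of these lists passed limma's camera (adjusted p = 0.905, 0.398, 0.226 and 0.325).

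The NF-kappaB genes rela and relb, which encode transcription factors of inflammation, rose. In the innate immune list 12 of 48 rose and 6 fell, with the same counts adjusted over the list alone (13 and 2 after median-of-ratios scaling). The levels of rela (14.97 to 32.0 TPM) and relb (4.08 to 7.68 TPM) rose beside socs3 and hamp, and tlr7 and irf8, chosen from the list after their values were seen, were among the falls. This list passed limma's camera (adjusted p = 0.0434), though not with an estimated correlation (adjusted p = 0.862), after median-of-ratios scaling (0.0970) or without control 1 (0.0516) or cold 4 (0.119), nor by fry (0.118). In the antioxidant list 9 of 44 rose and 7 fell, with the same counts adjusted over the list alone (12 and 6 after median-of-ratios scaling; camera adjusted p = 0.346). The metallothionein gene mt2 rose (2980.1 ± 489 to 5575 ± 603 TPM), and msrb2 (21.6 to 9.34 TPM), msrb1a (44.1 to 25.1 TPM) and gpx8 (10.4 to 5.65 TPM) fell.

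Few markers of tissues next to the brain were called, such as fshb of the pituitary, though the photoreceptor list had a mean log2 change of -0.73. In meninges 2 of 22 fell, ogn (7.17 to 4.39 TPM) and foxd1 (4.05 to 2.71 TPM), against 1 adjusted over the list alone, and slc13a4 (49.0 and 46.9 TPM) and dcn (30.4 and 24.8 TPM in control and cold) were not called. The call of foxd1 was lost without control 1 (limma adjusted p = 0.0631), control 3 (0.0859), cold 2 (0.0691) or cold 4 (0.0624), and after median-of-ratios scaling (0.0558). Meningeal calls became 1 without control 3 or cold 2. In pituitary 2 of 11 fell, six6 and fshb (8.88 to 4.17 TPM), also adjusted over the list alone (fry adjusted p = 0.00645), and pomc (14.9 and 15.2 TPM) was not called. In skeletal muscle 1 of 9, ckma (0.873 to 3.97 TPM), rose and 1, ryr1b (21.1 to 17.1 TPM), fell, also adjusted over the list alone, and Mb measured 2224 and 2055 TPM. In erythrocytes 1 of 13, nt5c3a (49.5 to 75.9 TPM), rose and 1, epb41 (57.1 to 44.0 TPM), fell, also adjusted over the list alone, and blvrb measured 51.3 and 50.3 TPM. Erythrocyte calls became 4 without control 2. In the photoreceptor list, which includes 3 GTPase genes that are not photoreceptor genes, 4 of 18 fell and 1, the GTPase gene rhob (31.3 to 42.4 TPM), rose (2 and 0 adjusted over the list alone), with a median log2 change of -0.56 and 9 members called without cold 2. Photoreceptor calls became 2 without control 2, control 4, cold 1 or cold 3, and 3 without control 3 or cold 4. The falls were the GTPase gene rhoaa (32.7 to 24.1 TPM), pde6b (1.40 to 0.564 TPM), pde6c and aanat2, whose call was lost whichever library was left out (limma adjusted p from 0.0518 to 0.110) and after median-of-ratios scaling (0.0738). The call of rhob held only without control 3 or cold 2 (limma adjusted p otherwise from 0.0549 to 0.0821), and rhoab measured 212 and 197 TPM. Named after their values were seen, the rod genes gngt1 and saga measured 0.673 and 0.609 TPM in control 1, 10.2 and 6.69 in control 2, 15.2 and 13.03 in control 3, 27.5 and 20.4 in control 4, and 13.7 and 9.97 in cold 2. In the other 3 cold libraries gngt1 was listed at 0 and saga at 0.0551 TPM or less. Levels of these rod genes thus differed widely within each group. Few calls therefore do not show that the libraries held equal amounts of neighbouring tissue. Of 35 splits of the 8 libraries into equal groups, 7 gave the photoreceptor list a mean shift of at least the real 0.640 (highest other 1.16). None of these lists passed limma's camera (adjusted p = 0.398, 0.416, 0.838, 0.340 and 0.340).

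Of the 45 lists, limma's camera called 12, 10 of them higher and 2 lower in cold, and 15 had an unadjusted p under 0.05. With an estimated correlation limma called 0 lists, 5 had an unadjusted p under 0.05, and the smallest adjusted p was 0.0661. fry called 23 lists, 9 higher and 14 lower, and 10 of camera's 12 were among them in the same direction. Among the lists that camera did not call, fry also called the thyroid list higher (adjusted p = 0.0228). It called the telencephalon (0.0483), hypothalamic (0.0263), radial glia (0.0120) and oligodendrocyte lists (0.0462) lower. Since fry compares a list with no other genes, its directions carry the median log2 change over all genes. That median was -0.09 as reported and -0.01 after median-of-ratios scaling. Median and mean log2 change differed in sign in 5 lists that camera did not call. In the neuropeptide, thyroid and cold-inducible lists the mean was above 0 and the median below, and in the antioxidant and fatty acid synthesis lists the reverse held. camera measures a list against all genes, and it gave the direction higher to the hypoxia and glycolysis lists although their medians and means were below 0.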

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

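The tests of the clock genes, the comparison of oxt with avp and the question of RNA integrity in the long genes were chosen only after the results were seen, as were the counts over other splits of the libraries for genes, for the number of lists and for single lists.

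For named genes and for gene counts per library, 382 sets of group values were searched for a value far from the other 3. The rule was Dixon's 95% limit on the gap over the range. It flagged 16 values, all of named genes, where about 19.1 would be flagged by chance. That baseline is uncertain, since most named genes were picked by low p or by groups that did not overlap, which favours small spread. In cold 3, chrnb1l stood at 5.08 TPM (others 0.0593 to 0.0634) and psmd13 at 175 (162 to 163). In control 1, fhl5 stood at 7.68 (4.93 to 5.34), pcsk2 at 224 (201 to 204) and rhoaa at 29.4 (33.5 to 34.1). In control 4, srsf1a stood at 102 (111 to 113), atp2a2a at 81.4 (76.8 to 77.0) and rhoab at 196 (216 to 218). In cold 1, sdf2l1 stood at 33.5 (29.3 to 29.9) and msrb1a at 28.0 (next 24.4). In cold 2, lgals3bp.3 stood at 2.01 (3.01 to 3.05) and lhx1 at 8.81 (11.9 to 12.3). In cold 4, serpinh1 stood at 5.28 (6.51 to 6.75), decr1 at 26.3 (lowest 24.8), srsf2a at 79.9 (68.8 to 70.5) and pde6b at 0.437 (0.593 to 0.622).

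For the number of changed genes, 1 of the 35 splits of the libraries into 4 and 4, the real split, gave 6914 genes. The highest of the others gave 15. This argues against chance without excluding it, since 35 splits can give no share under 0.0286. Mixed splits also hold the group difference in their residual spread, which lowers their counts. Chance cannot be excluded for the number of changed lists, since 13 of the 35 splits gave at least the real number of 12 and the highest of the others gave 18. For single lists, the real split gave the largest mean shift of the 35 splits in 18 of 45 lists, not corrected for the number of lists. These include 11 of the 12 called lists, such as the clock list (0.794, highest other 0.418), but not the ribosomal proteins (0.121, highest other 0.124). The 12 lists were picked by camera on the real split, so this is not independent support. In the other splits limma called 0 members of these 12 lists, which shows little, since it called at most 15 genes there in all.

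The rises of nr1d1, ciarta, dbpb and other clock genes were weighed against technical explanations. The fixed total of TPM values, by which rising abundant genes push others down, cannot raise a gene. The 21 clock genes picked for having risen are therefore no test of it. Log2 changes of the 3 that fell, per3, csnk1db and rorc, were -0.68, -0.68 and -1.44. After median-of-ratios scaling they were -0.59, -0.59 and -1.37. That scaling moved the median of all genes only from -0.09 to -0.01, so their kept calls (100%) could hardly have been lost. The sizes of these falls argue against the fixed total as their whole cause. That fish of the groups were collected at different times of day or phases of the clock could give such changes. This cannot be told apart from an effect of temperature, since 0 libraries have a collection time in their labels. A biological effect of cold on clock transcripts stays open as well.

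The spread of oxt and avp within groups may come from different amounts of preoptic tissue in the dissected pieces. Deviations of oxt and avp from their group means had r = 0.556 over 8 libraries (exact permutation p = 0.163), and r = 0.847 without the 2 libraries farthest out. The preoptic transcription factor genes otp and sim1a did not follow them clearly (r = 0.0749, exact permutation p = 0.866, and r = 0.0323 without the 2 libraries farthest out). With 8 libraries neither value decides, so unequal dissection and differences between fish cannot be told apart. Unequal dissection was not tested for the rod genes or for the falls of region markers such as nkx2.4a, six6, rx3 and lhx5. It stays open there too.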

How the results depend on the processing

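The 5 TPM filter, the array quality weights, the removal of control 4 and cold 2 together and the lists without misnamed symbols were chosen after seeing the data. Count-based tests (DESeq2 Wald, limma-voom without and with quality weights, a surrogate variable from svaseq) were not run, since they need read counts, and scaling by library totals alone equals the analysis as reported. For 189 named genes, 3389 alternative values gave 3278 of the same direction and side of the threshold, 60 that lost and 9 that gained a call, and 42 that reversed, all in genes not called.

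The gene count was 6702 (3407 higher, 3295 lower) with median-of-ratios scaling, 6769 with upper-quartile scaling, 6588 without a filter, 6890 with a pseudocount of 0.1, 7277 with array quality weights, 5532 without control 4 and cold 2, 5642 with the replicate number as a block (where oxtr lost its call, adjusted p = 0.0773), and from 5782 to 6387 with each library left out. A fold of at least 1.5 left 2489 genes (856 higher, 1633 lower) and an adjusted p under 0.01 left 4015 (1511 higher, 2504 lower), by construction. The 12 lists became 0 with an estimated correlation and 23 with fry, and 11 to 14 with each library left out. With exact symbols they became 9, since autophagy (adjusted p = 0.0847), optic tectum (0.0509) and innate immune genes (0.0509) lost their calls. The cause was not tested.

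Log2 changes that reversed were, after median-of-ratios scaling, mbpa 0.0169, s100b 0.0115, blvrb 0.0635, slc13a4 0.0396, pomc 0.0525, eno3 0.0814, pvalb7 0.0403 and pcp4 0.0763. After upper-quartile scaling they were blvrb 0.0214, pomc 0.0124, eno3 0.0391 and pcp4 0.0335, and with array quality weights slc13a4 0.0301, pomc 0.0579, eno3 0.0126 and pvalb7 0.00909. Without control 4 and cold 2 they were s100b 0.0486, slc13a4 0.166, pomc 0.177, eno3 0.0402 and pvalb7 0.0930. With each library left out the ranges were avp -0.0651 to 0.779, mbpa -0.173 to 0.00879, cd59a -0.0111 to 0.151, s100b -0.149 to 0.0377, fabp7 -0.0236 to 0.190, blvrb -0.137 to 0.0967, slc13a4 -0.164 to 0.0605, pomc -0.186 to 0.220, eno3 -0.0522 to 0.0828, pvalb7 -0.160 to 0.0609 and pcp4 -0.0545 to 0.0375. The cause was not tested.

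Other named calls lost were those of edn1 (adjusted p = 0.106), foxd1 (0.0723) and aanat2 (0.106) without control 4 and cold 2, pcsk2 (0.0717), cyp19a1b (0.0544), rhob (0.0676) and aanat2 (0.102) with the replicate block, and edn1 (0.0619) and foxd1 (0.0589) without a filter. Calls gained were apoeb (0.0208) and cd74b (0.0413) without control 4 and cold 2, and cldn5 (0.0296) with the block.

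Depth limits low genes, but its absolute value is not recoverable from TPM.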

Other observations

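The test of RNA integrity and the bound from leaving out the lowest genes were chosen only after the results were seen, and the families by symbol stem and the gene spans were chosen after the data were seen.

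Genes with long genomic spans were lower in cold. Of 16603 genes with a span, the 1661 longest (at least 50866 bp) had a median log2 change of -0.18, against -0.07 in the rest, with 71 members higher and 514 lower (115 and 362 after median-of-ratios scaling). For this difference 1 of the 35 splits of the libraries, the real split, gave 0.108 and the highest of the others gave 0.0794. Chance is not excluded by this, since 35 splits can give no share under 0.0286 and the spans were chosen after the data were seen. Expression level is argued against as its cause, since a permutation test with 10000 gene sets matched on expression gave p = 0.0001, the smallest they can give. That neuronal signalling genes, which are long, fell stays open, since leaving out the 91 listed ones (difference -0.107) could not have decided it, as leaving out the 91 lowest would still give -0.0910. Lower RNA integrity in the cold libraries, which would cost long transcripts reads, also stays open beside an effect of cold, since 0 libraries have an RNA integrity value in their labels. The spans are genomic, and the length of the transcripts was not measured.

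Among 167 families of at least 10 genes sharing a symbol stem, limma's camera called 4, with 25 at an unadjusted p under 0.05 and 0 with an estimated correlation (adjusted p = 0.928 for the lowest). The Kruppel-like factor genes (klf, 9 of 17 higher and 2 lower, adjusted p = 0.00855) and the F-box genes (fbxl, 7 of 17 higher and 2 lower, 0.0399) were called higher. The axon guidance genes of the semaphorins (sema, 16 of 26 lower, 0.0261) and the adhesion genes of the protocadherins (pcdh, 10 of 13 lower, 0.0291) were called lower. After median-of-ratios scaling these 4 kept their directions and calls. The families psmd, nup and rpl were then called higher too (camera adjusted p = 0.0206, 0.0371 and 0.0147). Chance cannot be excluded for the number of families called as reported, since 10 of the 35 splits gave at least the real number of 4 families and the highest of the others gave 17.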
